A study of Homo sapiens with 38 samples.

How the data were processed

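Total RNA of human HEK-293 lines was measured on 38 Illumina expression arrays, each with 47231 probes. Per the labels' protocols, RNA was extracted with an RNeasy kit, had an integrity number above 8, and was turned into biotinylated cRNA with the Ambion TotalPrep kit. The deposited table of non-normalised values holds 1 probe signal (intensity, linear scale) per array and gives no detection p-values. The other deposited table, the series matrix, holds log2 values, and neither labels nor headers state how they were made. Its values lie within 0.0301 log2 of a quantile normalisation of the log2 signals without background correction, computed here as a check.

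The deposited intensities were corrected for background with the normexp model (offset 50), turned into log2 values and quantile normalised. The offset pulls small signals towards each other, so the fold changes given are compressed for dim probes. The planned Illumina-specific correction needs detection p-values. In their place, a detection p was estimated per array from the mode of the log2 signals and the spread below that mode, and probes with an estimated p under 0.05 on at least 3 arrays were kept (33274 probes). Median raw signal per array ran from 81.5 to 112 (median 103) against a background mode of 78.3 to 98.5, and 41.4% to 58.8% of probes were detected. Signal over background and the number of arrays set the precision; the residual standard deviation had a median of 0.104 log2 over genes.

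Probe names come from the platform annotation supplied with the data, which can be old, so symbols were updated through the gene identifier with a RefSeq gene table (assembly GRCh38.p14, used for names only). Of the probes, 30113 had 1 symbol, 8 had several and 17110 were unnamed in that annotation, and 30074 symbols were found by gene identifier. Of the probes kept, 22487 were named, and each gene was read from its probe of highest mean, which left 16039 genes tested. HERPUD1 had no named probe and was not analysed here.

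Samples were grouped by the labels: 13 groups of 3 arrays, except 2 mock arrays in the alpha-1-antitrypsin line. The labels number the arrays without shared replicate numbers, so no pairing was assumed. They do not say whether arrays of a group come from separate cultures, so p-values measure the spread between samples, which may be technical. For 1 array the title names the CD3δ line and the description the CD3δ qqq line; it was used as CD3δ qqq Tet 2. The alpha-1-antitrypsin variant is written alpha1AT-C-D64A in titles and α1AT-C-D6A in descriptions, and the line is called a1AT below. Treatment times are not in the labels, and no line without a transgene was included, so the effect of tetracycline itself cannot be separated.

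Group means were fitted to all 38 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, residual df 25, prior df 11.2). The 15 contrasts were Tet against mock in 5 lines, each drug against mock and against Tet in the BACE457 line, 5 µg/ml against 40 ng/ml tunicamycin, thapsigargin against 40 ng/ml tunicamycin, and differences of Tet effects between BACE457Δ and BACE457 and between CD3δ qqq and CD3δ. P-values were adjusted by Benjamini and Hochberg over the genes, with a threshold of 0.05. Differences are log2 values ± standard error of that fit, with n = 3 arrays per group unless stated.

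Before the data were examined, 24 lists with 475 genes were fixed, of which 426 were tested: ER multichaperone complex, ER cochaperones, calnexin and calreticulin cycle, oxidative folding, ER-associated degradation (ERAD), sensors and factors of the unfolded protein response (UPR), PERK-ATF4-CHOP targets, ATF4 amino acid genes, cytosolic tRNA synthetases, translocation and signal peptidase, N-glycosylation, COPII and COPI transport, cholesterol synthesis, cytosolic heat shock, proteasome, cell cycle, calcium handling, NRF2 targets, p53 targets, immediate early genes, ribosomal proteins, and markers of T cells, hepatocytes and carcinoma lines. Lists were tested with camera at its preset correlation, adjusted over the 24 lists of a contrast. They were tested again with an estimated correlation and with fry. Camera p-values are at the preset correlation unless stated. For the ER multichaperone complex the estimated correlation was 0.377, above the preset, so its p-values at the preset overstate the evidence. For each drug against mock, the call of this list held with the estimated correlation. Members were also counted after adjustment over the list alone. The series title names an ER complex that binds unfolded proteins, so the direction of the ER multichaperone complex list is not independent evidence.

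Named genes follow a rule fixed at the same time: the 5 largest rises and falls past the threshold (in contrasts with mock, only where arrays of the groups did not overlap), all members of the ER multichaperone complex, 8 stress genes, up to 3 members of each other list in contrasts with mock, and CD3D, BACE1 and SERPINA1. Simulated data had the real arrays' spread (20 draws, 200 changed genes each). For tunicamycin at 5 µg/ml against mock, the steps recovered 50.7% of 1.25-fold and 96.5% of 1.5-fold changes (mean false share 4.86%). For BACE457 Tet against mock they recovered 49.0% and 95.9% (mean false share 4.96%). Simulated genes varied independently, and 200 changes ease the adjusted threshold. Where few genes change, fewer changes of these sizes would pass, so 0 calls with Tet do not exclude them. HSPA5, at 1.62-fold in BACE457 Tet against mock, did not pass.

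Alternatives were the series matrix values, no background correction, median scaling in place of quantile normalisation, no detection filter (20046 genes), a strict filter (13057 genes), a fit of the compared groups only, all named probes, eBayes with trend and robust, array weights, a 1.5-fold minimum, the number range of the array titles as a term, the doubtful array moved to the CD3δ line, and each array left out. The planned chip block was not run, since the deposited files give no chip.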

Results

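Transcript levels were measured in human embryonic kidney (HEK-293) lines that carry a tetracycline-inducible (Tet) transgene for a secretory-pathway protein. The labels describe these proteins as model polypeptides. They were BACE457, a splice isoform of the protease beta-secretase, its variant BACE457Δ, CD3δ, a T-cell receptor subunit, its variant CD3δ qqq, and a variant of alpha-1-antitrypsin (a1AT), a secreted protease inhibitor encoded by SERPINA1. Each line had 3 arrays with 100 ng/ml Tet and 3 mock arrays, except for 2 mock arrays in the a1AT line. The BACE457 line also had 3 arrays each with tunicamycin, which blocks N-glycosylation, at 5 µg/ml and at 40 ng/ml, and with thapsigargin, which blocks the calcium pump of the endoplasmic reticulum (ER), at 25 nM. The comparisons ask how the responses to drugs and to an expressed polypeptide differ.

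SERPINA1, the gene of the transgene in the a1AT line, had log2 values of 13.11 and 13.17 on a1AT Tet 1 and 2, against 8.36 and 8.52 on the mock arrays of that line. The array labelled a1AT Tet 3 stood at 8.54. On the same probe the mock means of the other lines ran from 6.11 (BACE457Δ) to 6.18 (BACE457). SERPINA1 was thus higher in the a1AT line without Tet as well. Its mock arrays may not be free of transgene expression, which was not tested. SERPINA1 was 3.17 ± 0.58 higher with Tet over all 5 arrays (9.0-fold, adjusted p = 0.0515), and 4.70 ± 0.10 higher without a1AT Tet 3 (adjusted p = 2.91e-31). On the probes used, CD3D and BACE1 differed between Tet and mock by at most 0.17 in any line and passed no test, and the other CD3D probe differed by 0.287 in the CD3δ line. These probes may lie outside the expressed cDNA and so check no label. In the a1AT line, 3 arrays (Tet 1, Tet 2 and mock 1) stood apart from all others on the first principal component, at -23.7, -24.5 and -21.3 against at most 11.4 in absolute value elsewhere.

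**Figure D1:**
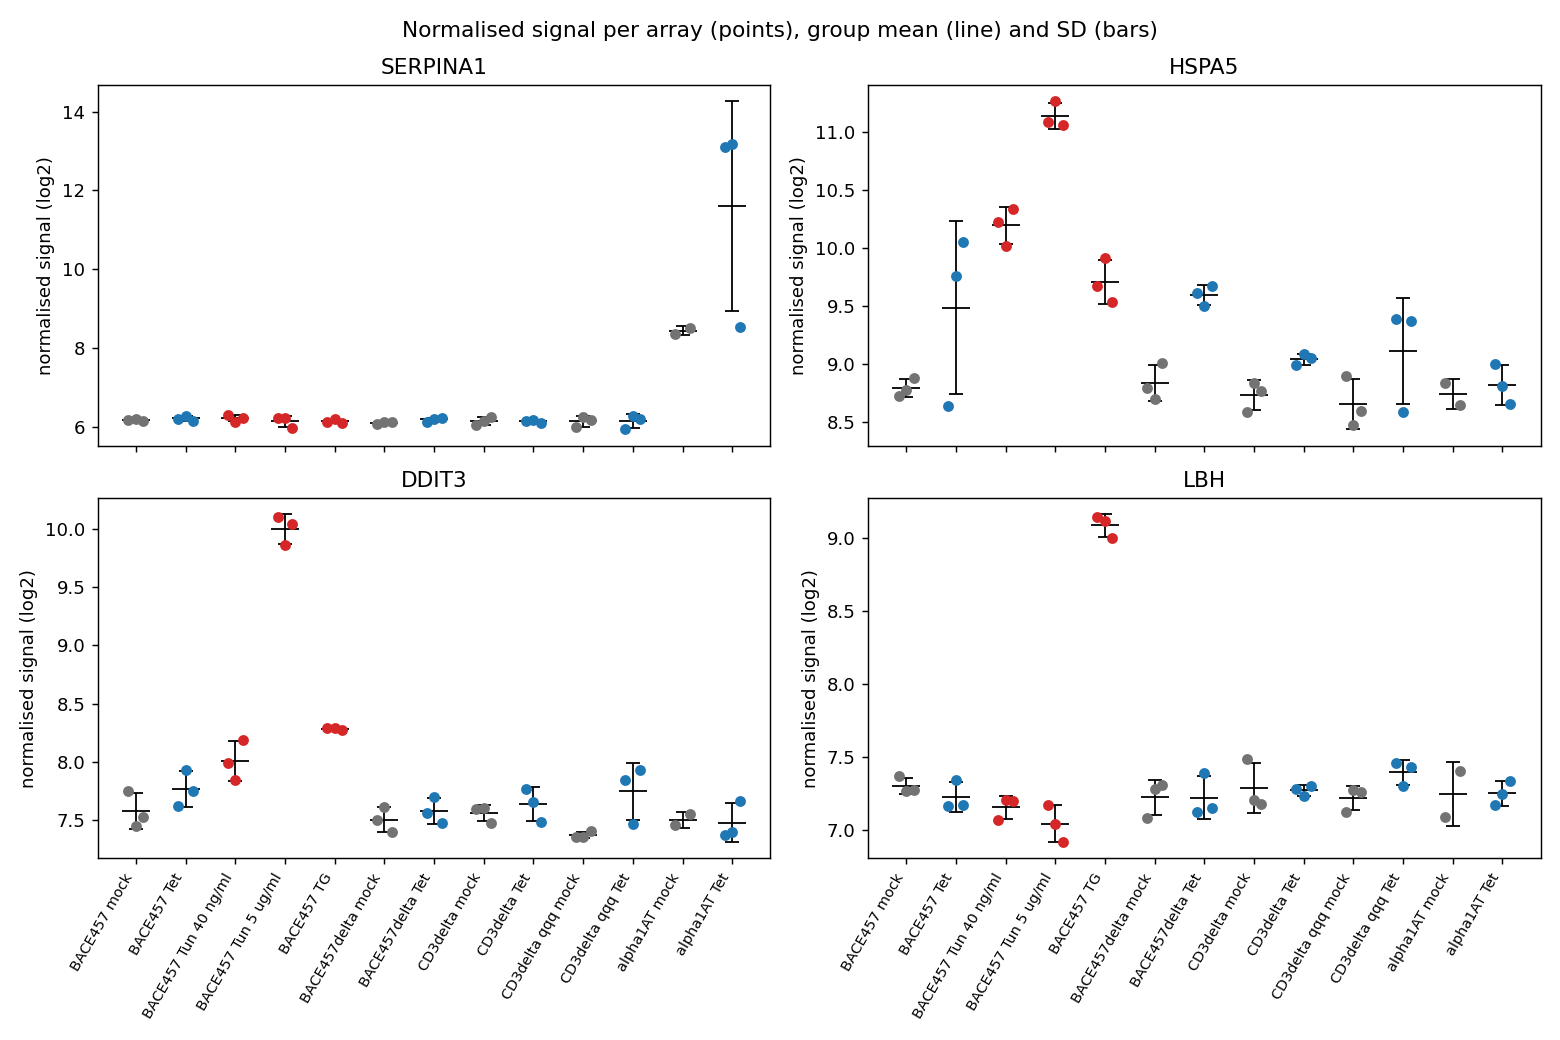
Log2 normalised signal (y axis) of SERPINA1, HSPA5, DDIT3 and LBH on each array, by group (x axis), with points for arrays and bars for the group mean and standard deviation. SERPINA1 stands at 13.11 and 13.17 on 2 of the a1AT Tet arrays and at 8.54 on the array labelled a1AT Tet 3.

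Tunicamycin at 5 µg/ml gave the widest response to a drug in the BACE457 line. DDIT3, which encodes the stress transcription factor CHOP (probe ILMN_1676984), rose by 2.43 ± 0.10 on the log2 scale (5.38-fold, adjusted p = 4.47e-19). HSPA5, which encodes the ER chaperone BiP (probe ILMN_1773865), rose by 2.35 ± 0.20 (5.09-fold, adjusted p = 2.64e-11). TRIB3, a pseudokinase downstream of ATF4, rose 3.95-fold, and CRELD2, a secreted ER stress protein, rose 3.87-fold. SLC6A9, a glycine transporter, rose 4.70-fold on the probe used, while its other probes differed by -0.0065 and 0.055. Of the 16039 genes, 595 rose and 512 fell, 127 and 35 of them by at least 1.5-fold, in limma's test.

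Genes of the ER folding machinery rose together. In the ER multichaperone complex, 9 of 10 members rose (10 adjusted over the list alone, camera adjusted p = 3.09e-34 at the preset correlation). These included the chaperone HSP90B1 (2.51-fold), the HSP70 homologue HYOU1 (3.04-fold), the cochaperones DNAJB11 (2.05-fold) and SDF2L1 (3.33-fold), and the disulfide isomerases PDIA4 (3.16-fold) and PDIA6 (2.34-fold). UGGT1, the glycoprotein folding sensor, differed by 0.29 ± 0.10 (adjusted p = 0.0622) and did not pass over all genes. Among the ER cochaperones, 8 of 16 rose (10 over the list alone, adjusted p = 3.04e-17), with MANF, a BiP-binding factor, up 3.08-fold. In the calnexin and calreticulin cycle, 5 of 10 rose (5 over the list alone, adjusted p = 6.02e-07), CALR 2.04-fold and CANX 1.87-fold. Of the sensors and factors of the UPR, 3 of 9 rose (4 over the list alone, adjusted p = 7.04e-06), XBP1 2.0-fold. Lists of ER translocation (11 of 23, 14 up and 2 down over the list alone, adjusted p = 1.79e-09) and N-glycosylation (9 of 29, 12 over the list alone, adjusted p = 2.39e-09) also rose. DPAGT1, the enzyme that tunicamycin inhibits, rose 1.56-fold. ATP2A2, the pump that thapsigargin inhibits, rose 1.37-fold, a call lost without 5 µg/ml tunicamycin array 2 (adjusted p = 0.0556).

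In 5 lists that rose after quantile normalisation, the median turned negative with median scaling, which also moved the median of all genes to -0.078. These were oxidative folding (5 of 16 rose, 6 over the list alone, adjusted p = 1.72e-06; median -0.11 with median scaling), ERAD (10 of 27, 12 over the list alone, adjusted p = 6.44e-10; -0.0013), tRNA synthetases (9 of 18 rose and 1 fell, 12 and 1 over the list alone, adjusted p = 1.10e-10; -0.0020), COPII and COPI transport (8 of 26, 12 up and 2 down over the list alone, adjusted p = 0.000230; -0.14) and calcium handling (5 of 20 rose and 1 fell, 6 and 1 over the list alone, adjusted p = 0.000165; -0.042). Set against the median of all genes, ERAD (0.076), tRNA synthetases (0.076) and calcium handling (0.036) stayed higher, while oxidative folding (-0.028) and COPII and COPI transport (-0.058) lay lower. Single members stood out in them: DERL3, an ERAD factor, rose 3.07-fold (other probe 0.481 on the log2 scale), PDIA5, a disulfide isomerase, 1.77-fold, WARS1, a tRNA synthetase, 1.99-fold, and NUCB2, a calcium-binding protein, 1.82-fold.

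Targets of the kinase PERK and of ATF4 rose in large shares. Of the PERK-ATF4-CHOP list, 16 of 20 rose (18 over the list alone, adjusted p = 4.35e-41), including INHBE, an inhibin subunit, at 2.81-fold. Of the ATF4 amino acid genes, 18 of 20 rose (18 over the list alone, adjusted p = 7.64e-45), including the transporter subunit SLC3A2 (3.10-fold) and asparagine synthetase, ASNS (2.48-fold). Genes that fell were led by ETV5, a transcription factor downstream of ERK signalling, which fell by 1.86 on the log2 scale (SE 0.12, adjusted p = 2.72e-14), with its other probe at -0.56. DUSP6, a phosphatase of ERK, fell by 1.07 (other probe -0.16), PIR, an iron-binding nuclear protein, by 1.01, and SPRED1 and SPRED2, inhibitors of the same pathway, fell by 0.87 and fell by 0.78.

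Cytosolic heat shock genes fell, with 8 of 15 down (10 over the list alone, adjusted p = 2.04e-09), among them HSPA1B, which fell by 0.58, and HSPH1, which fell by 0.46. Proteasome subunits (7 of 27 down, 12 over the list alone, adjusted p = 8.57e-09), cell cycle genes (8 of 34, 10 over the list alone, adjusted p = 7.19e-05) and cholesterol synthesis genes (5 of 18, 6 over the list alone, adjusted p = 0.00308) fell too. PSMD11 and PSMD1, subunits of the proteasome lid and base, fell by 0.60 and fell by 0.57. CCNA2, a cyclin, fell by 0.44, and MSMO1, a sterol oxidase, fell by 0.60 (other probes -0.108 and -0.722). These 4 directions and those of the complex, cochaperone, calnexin, UPR, PERK, ATF4, translocation and N-glycosylation lists were the same with median scaling. That scaling put the median of all genes at -0.078, on the side of the 4 falls, so their kept sign alone says little. Ribosomal protein genes passed as a list (adjusted p = 0.0188, median 0.045, no single member called), but not with an estimated correlation (adjusted p = 0.0872 with an estimated correlation), without mock 1 (0.0857), or without 5 µg/ml array 3 (0.0672), and their median was -0.030 with median scaling, which is 0.048 above the median of all genes. No shift passed for immediate early genes (3 up and 4 down of 15, 3 and 5 over the list alone, adjusted p = 0.192), NRF2 targets (1 down of 11, 1 up and 1 down over the list alone, 0.445), p53 targets (median 0.03, mean -0.0012, 0.889), or markers of T cells (0.814), hepatocytes (0.742) and carcinoma lines (1 up and 1 down of 5, 2 and 2 over the list alone, 0.814). With median scaling, 83 genes were called (42 up, 41 down). The count fell to 709 without mock 2 and to 673 without 5 µg/ml array 3, the dimmest array.

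**Figure D2:**
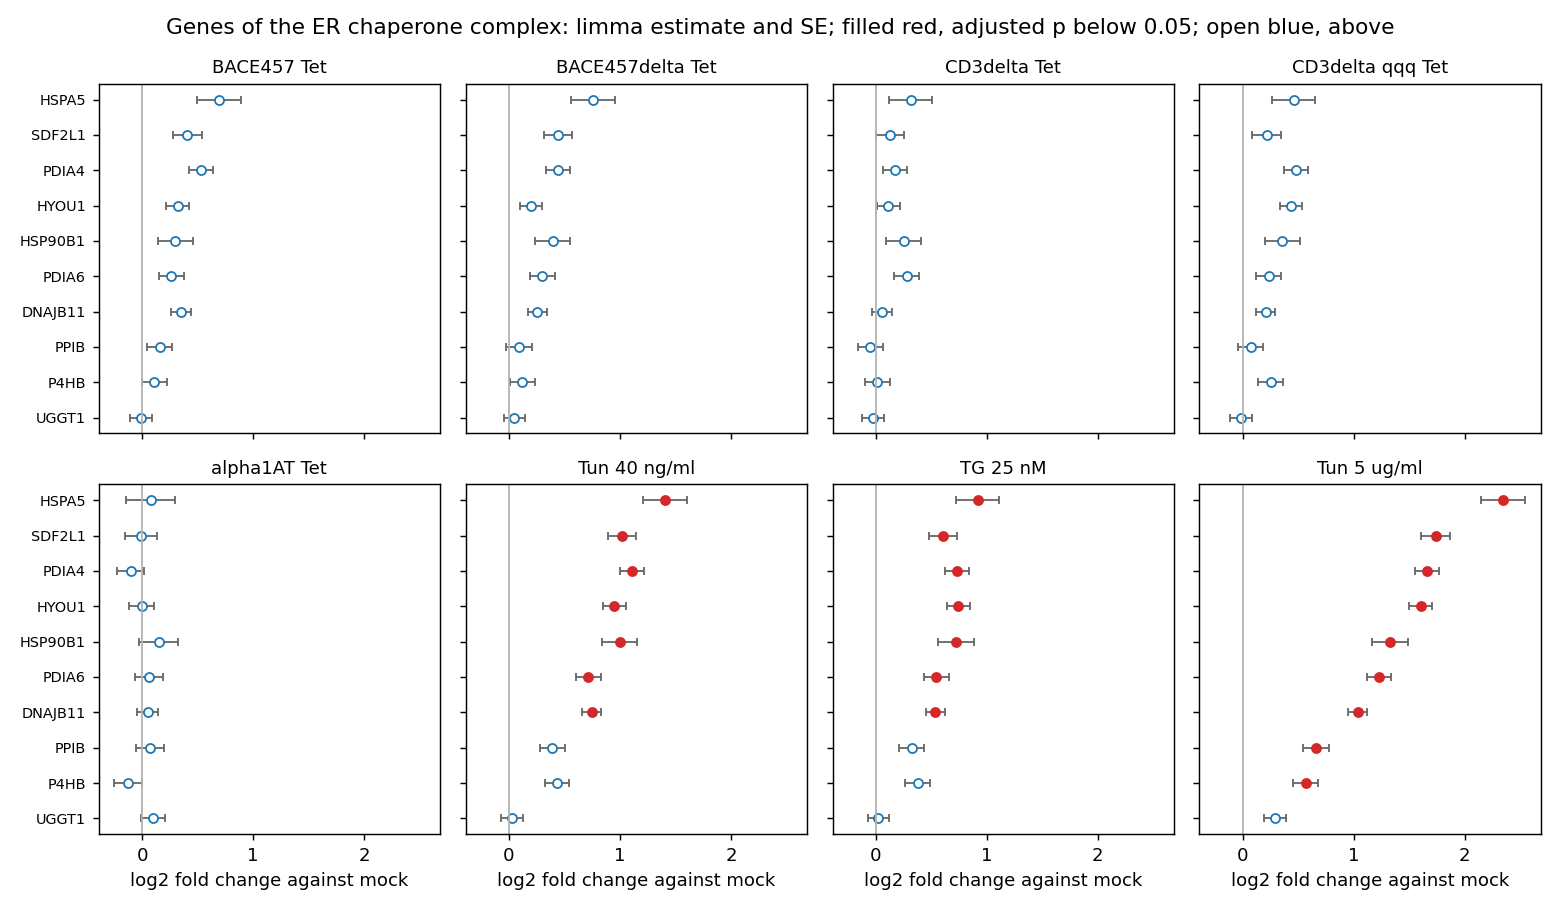
Log2 difference (x axis) ± standard error of the 10 genes of the ER multichaperone complex in 8 contrasts (panels), filled red where the adjusted p lies under 0.05 and open blue where it does not. With tunicamycin at 5 µg/ml, 9 of the 10 pass, and with Tet none does.

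Tunicamycin at 40 ng/ml raised a narrow set of genes, and no gene fell past the threshold in the fit of all arrays. Falls numbered 47 (and rises 142) when only the compared groups were fitted, 94 (and 158) with array weights, and 4 (and 51) with the series matrix values. HSPA5 rose by 1.40 ± 0.20 (2.65-fold, adjusted p = 2.63e-05), CRELD2 by 1.29 ± 0.13 (2.44-fold), PDIA4 by 1.11 ± 0.11 (2.16-fold), SDF2L1 by 1.02 ± 0.13 (2.03-fold) and HSP90B1 by 1.0 ± 0.16 (2.0-fold). DDIT3 differed by 0.43 ± 0.10 (adjusted p = 0.0684), TRIB3 by 0.46 ± 0.12 (0.0878), and XBP1 by 0.13 ± 0.11 (0.857), none of which passed. In all, 48 genes rose, 19 of them by at least 1.5-fold.

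Of the ER multichaperone complex, 7 of 10 members rose (9 over the list alone, adjusted p = 2.30e-38), with HYOU1 at 1.93-fold, DNAJB11 at 1.68-fold and PDIA6 at 1.64-fold. P4HB, a disulfide isomerase, differed by 0.43 (adjusted p = 0.102), PPIB, a cyclophilin, by 0.39 (0.176) and UGGT1 by 0.03 (0.987). ER cochaperones rose (6 of 16, 7 over the list alone, adjusted p = 1.37e-16), with MANF at 1.68-fold. ATF4 amino acid genes rose as well (5 of 20, 9 over the list alone, adjusted p = 6.87e-18), ASNS by 1.80-fold. Smaller groups of members rose in the lists of translocation (2 of 23, 7 over the list alone, 2.68e-09), ERAD (2 of 27, 5 over the list alone, 1.37e-06), PERK-ATF4-CHOP targets (1 of 20, 4 over the list alone, 3.70e-05), N-glycosylation (1 of 29, 5 over the list alone, 0.000215) and the calnexin and calreticulin cycle (2 of 10, 2 over the list alone, 0.000396). DERL3 rose 1.84-fold (other probe 0.114 on the log2 scale) and EIF4EBP1, a translation inhibitor, 1.49-fold. The tRNA synthetase list (adjusted p = 0.0176, 1 of 18 up, 2 over the list alone) lost its call with an estimated correlation (adjusted p = 0.0648 with an estimated correlation) and without 40 ng/ml array 1 (0.125). Its median was -0.035 with median scaling, which is 0.0061 above the median of all genes. The cholesterol list (0.0146, 0 of 18, 1 over the list alone) lost its call likewise (adjusted p = 0.0700 with an estimated correlation; 0.170 without mock 2; 0.0725 without 40 ng/ml array 2). With median scaling, 2 genes were called, CRELD2 and SDF2L1, and without 40 ng/ml array 2 the count was 29.

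Thapsigargin raised genes outside the ER lists most. LBH, a transcription cofactor (probe ILMN_2315979), rose by 1.78 ± 0.09 (3.43-fold, adjusted p = 5.72e-17), and its other probe by 0.827. RGS2, a regulator of G-protein signalling, rose 2.74-fold, SLC3A2 2.46-fold, PPEF1, a calcium-binding phosphatase, 2.38-fold, and NEU1, a lysosomal sialidase, 2.04-fold. AMOT, a scaffold of cell junctions, fell by 0.85 (SE 0.12, adjusted p = 2.57e-05). IGFBP5, a binding protein of insulin-like growth factors, fell by 0.84 (SE 0.18, adjusted p = 0.0038), a call lost without thapsigargin array 2 (-0.58, adjusted p = 0.127). NR2F1, a nuclear receptor, HOXC13, a homeobox factor, and S100A10, a calcium-binding-family protein, fell by 0.66, fell by 0.61 and fell by 0.61. In all, 179 genes rose and 137 fell, 42 and 8 of them by at least 1.5-fold.

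In the ER multichaperone complex, 7 of 10 members rose with thapsigargin (9 over the list alone, adjusted p = 5.92e-19), with HYOU1 at 1.67-fold, PDIA4 at 1.66-fold, PDIA6 at 1.46-fold and DNAJB11 at 1.45-fold. HSPA5 rose by 0.92 ± 0.20 (1.89-fold, adjusted p = 0.00518), HSP90B1 1.65-fold and SDF2L1 1.52-fold, and TRIB3 rose 1.48-fold. Leaving out thapsigargin array 2 ended these 4 calls (HSPA5 0.81 ± 0.22, adjusted p = 0.0656; HSP90B1 0.0672; SDF2L1 0.0663; TRIB3 0.0524). P4HB (0.38, adjusted p = 0.0764), PPIB (0.32, 0.172) and UGGT1 (0.02, 0.983) did not pass. DDIT3 rose 1.64-fold and DNAJB9, a cochaperone of BiP, 1.66-fold. XBP1 rose 1.37-fold, a call lost without mock 2 (adjusted p = 0.113), mock 3 (0.0918) or thapsigargin array 1 (0.133).

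Of the ATF4 amino acid genes, 9 of 20 rose with thapsigargin (13 over the list alone, adjusted p = 6.71e-21), and of the PERK-ATF4-CHOP targets 7 of 20 (10 over the list alone, 2.48e-14), with ATF3, a stress transcription factor, at 1.82-fold (other probe 0.097 on the log2 scale) and STC2, a glycoprotein hormone, at 1.59-fold. Members also rose in the lists of ER cochaperones (7 of 16, 9 over the list alone, 3.68e-15), translocation (4 of 23, 5 over the list alone, 1.96e-05), ERAD (2 of 27, 4 over the list alone, 2.02e-06), UPR sensors and factors (1 of 9, 4 over the list alone, 0.00115), N-glycosylation (2 of 29, 4 over the list alone, 0.00929) and cholesterol synthesis (1 of 18, 3 over the list alone, 0.000761). The N-glycosylation calls, GFPT1 and RPN1, and the cholesterol call, HMGCS1, were lost without mock 2 (adjusted p = 0.116, 0.216 and 0.0981). Oxidative folding genes shifted up as a list (0 of 16, 1 over the list alone, 0.000761). The calls of the calnexin cycle (3 of 10, 4 over the list alone, 0.00929) and of tRNA synthetases (3 of 18, 4 over the list alone, 0.00197) were lost without thapsigargin array 3 (0.0901 and 0.0574). Immediate early genes went both ways (4 up and 2 down of 15, 5 and 2 over the list alone, 0.0207), with JUN at 1.49-fold and DUSP1 at 1.46-fold, and the list's call was lost without array 2 (0.122) and with an estimated correlation (adjusted p = 0.147 with an estimated correlation). The medians of all these lists kept their sign with median scaling. That scaling put the median of all genes at 0.024, on the side of the rises. CD44, among the carcinoma markers, rose 1.59-fold (other probes 0.081 and 0.21 on the log2 scale), though that list did not pass (0.0726, 1 of 5). With median scaling, 20 genes were called (19 up, 1 down), with LBH, RGS2, SLC3A2, PPEF1, NEU1 and ASNS among them. The count moved to 177 without mock 2, 179 and 155 without thapsigargin arrays 1 and 2, and 485 without array 3.

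The 3 drug treatments shared rises. All 35 genes called with every drug rose. Of the 48 genes that rose with tunicamycin at 40 ng/ml, 45 rose at 5 µg/ml (1.78 expected of independent lists) and 36 rose with thapsigargin (0.536 expected). Tunicamycin at 5 µg/ml and thapsigargin shared 111 rises and 64 falls (6.64 and 4.37 expected), with 2 genes in opposite directions. Unchanged groups simulated against the same mock arrays shared 0 calls. Groups without change give almost no calls, so this value cannot show how much overlap shared mock arrays add. The mock arrays are common to these contrasts and were not split for these counts, so part of the excess may come from them.

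With Tet, no gene passed limma's test over all genes in any of the 5 lines in the fit of all arrays. Genes with an unadjusted p under 0.05 numbered 309 (BACE457), 231 (BACE457Δ), 325 (CD3δ), 574 (CD3δ qqq) and 530 (a1AT), below the 802 that chance alone gives. Non-overlapping arrays were seen for 8.40%, 6.12%, 7.34% and 6.48% of genes in the first 4 lines, where chance gives 10%, and for 10.6% in the a1AT line, where chance gives 20%. Changes of gene groups were tested as lists. A fit with arrays of adjacent title numbers as a block was chosen after seeing the data, in which the 8 most alike mock and Tet arrays of a line have adjacent numbers. The labels give no such pairing. In that limma fit 7 genes passed in BACE457Δ: HSPA5 (adjusted p = 5.03e-05), MANF, CRELD1, PDIA4, SDF2L1, CRELD2 and, downwards, OAZ2, an antizyme regulating polyamines. In CD3δ 1 passed, EIF3CL (0.51, adjusted p = 0.0381), and in CD3δ qqq 0. CRELD1, OAZ2 and EIF3CL were named after their values were seen. Adjusted over the list alone, 7, 4 and 8 of the 10 members of the ER multichaperone complex passed in BACE457Δ, CD3δ and CD3δ qqq.

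In the BACE457 line, ER chaperone genes lay higher with Tet as a group, on Tet 2 and 3 but not on Tet 1. The BACE1 probes, which may lie outside the expressed cDNA, do not show whether the transgene was induced. An effect of tetracycline itself cannot be separated. The ER multichaperone complex had a median difference of 0.31 (camera adjusted p = 6.99e-17; 0.00180 with an estimated correlation), with 6 of 10 members up adjusted over the list alone and 0 over all genes. HSPA5 differed by 0.69 ± 0.20 (1.62-fold), PDIA4 by 0.53 ± 0.11 (1.44-fold) and SDF2L1 by 0.41 ± 0.13 (1.33-fold). The mean over the complex, set against the mock mean, was -0.033 on BACE457 Tet 1 and 0.456 and 0.515 on Tet 2 and 3. BACE457 Tet 1 and mock 1, with adjacent title numbers, had a standard deviation of differences of 0.108. Ranked by likeness, they were pair 2 of the mock and Tet pairs within lines. Pairs 1 and 3 held a1AT Tet 3 and CD3δ qqq Tet 2. Whether BACE457 Tet 1 was mislabelled or not induced was not tested, since no probe checks its label. Without BACE457 Tet 1, 9 genes passed over all genes: HSPA5 (1.12 ± 0.16), PDIA4 (0.73), MANF (0.65), CRELD2 (0.63), SDF2L1 (0.62), CRELD1 (0.61), DNAJB11 (0.49), TRIM5 (0.48) and HYOU1 (0.47). Without mock 1, 2 passed, ISL1 (-0.73) and RAB32 (0.45). These genes outside the naming rule, TRIM5, CRELD1, ISL1 and RAB32, were chosen after their values were seen. ER cochaperones (median 0.12; 4.78e-08; 2 members over the list alone, CRELD2 and MANF) and ERAD genes (0.07; 0.000544; 2 over the list alone, DERL3 and SYVN1) shifted up too, both with an adjusted p of 0.00180 with an estimated correlation. Oxidative folding (0.04; 0.00427) lost its call without mock 1 (0.0685) and Tet 3 (0.154). The calls of ATF4 amino acid genes (0.00694), COPII and COPI transport (0.0185) and cholesterol synthesis (0.00921) were lost (adjusted p = 0.205, 0.199 and 0.0947 with an estimated correlation).

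In the BACE457Δ line the same complex had a median difference of 0.28 (8.00e-18; adjusted p = 0.00357 with an estimated correlation; 6 of 10 over the list alone), a call lost with fry (adjusted p = 0.0792 with fry). HSPA5 differed by 0.76 ± 0.20 (1.69-fold), PDIA4 by 0.45 ± 0.11 (1.36-fold) and SDF2L1 by 0.44 ± 0.13 (1.36-fold), and the complex mean lay 0.339, 0.275 and 0.301 above the mock mean on the 3 Tet arrays. ER cochaperones had a median of 0.08 (7.46e-06; 3 over the list alone), a call lost with fry too (adjusted p = 0.101 with fry). The calnexin cycle (0.00392; 2 over the list alone) and COPII and COPI transport (0.00246) passed, but not with an estimated correlation (adjusted p = 0.0504 and 0.0782 with an estimated correlation). When only the groups of this line were fitted, 6 genes passed over all genes: HSPA5, MANF, CRELD1, PDIA4, SDF2L1 and, downwards, OAZ2. The difference between the BACE457Δ and BACE457 effects passed for no gene in limma (219 at an unadjusted p under 0.05) and for no list.

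In the CD3δ qqq line, the complex had a median difference of 0.24 (8.21e-11; adjusted p = 0.0401 with an estimated correlation; 2 members over the list alone, HYOU1 and PDIA4), a call lost with fry (adjusted p = 0.0719 with fry), as were all other list calls of this line. HYOU1 differed by 0.44 ± 0.10, PDIA4 by 0.48 ± 0.11 and HSPA5 by 0.46 ± 0.20. Per array, the complex mean lay 0.45 and 0.34 above mock on Tet 1 and 3 and 0.015 on Tet 2, the array whose title and description name different lines. COPII and COPI transport genes had a median of 0.08 (0.000162; adjusted p = 0.0871 with fry). ER cochaperones (0.00127; 2 over the list alone) lost their call without Tet 3 (0.126). UPR sensors and factors (0.0132) lost it without mock 1 (0.194), Tet 1 (0.172) or Tet 3 (0.112), and N-glycosylation (0.0235) without Tet 1 (0.471), mock 2 (0.278) or Tet 3 (0.126). PERK-ATF4-CHOP targets (0.0132), ATF4 amino acid genes (0.000183) and translocation (0.0132) lost theirs (adjusted p = 0.189, 0.0589 and 0.0906 with an estimated correlation). In the CD3δ line the complex had a median of 0.12 (0.00999), a call lost with an estimated correlation (adjusted p = 0.458 with an estimated correlation), without CD3δ Tet 2 (0.0855) and without mock 3 (0.0984), with 0 members over the list alone. Its mean lay 0.107, 0.142 and 0.125 above mock on the 3 CD3δ Tet arrays, and between -0.0074 and 0.0069 on the mock arrays. The CD3δ qqq and CD3δ effects differed for no gene (356 at an unadjusted p under 0.05).

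In the a1AT line no list passed (complex: median 0.06, adjusted p = 0.624), and HSPA5 differed by 0.08 ± 0.22 (n = 3 and 2). Without a1AT Tet 3, 4 genes passed: SERPINA1, NUCB2 (0.60 ± 0.11) and, downwards, ARPC2 (-0.51 ± 0.10) and HIF3A (-0.48 ± 0.09), the last 3 named after their values were seen. Both Tet arrays left in that fit are among the 3 arrays that stood apart, against 1 of the 2 mock arrays, so the last 3 calls cannot be told from that separation. The medians of the lists called in the other 4 lines kept their sign with median scaling. That scaling put the median of all genes at 0.052 in CD3δ qqq, 0.018 in BACE457, 0.0083 in BACE457Δ and -0.011 in CD3δ. In CD3δ qqq the medians of PERK-ATF4-CHOP targets (0.050) and N-glycosylation (0.052) were no larger than that. A kept sign therefore says little for such lists. In the BACE457 line, fold changes with Tet correlated with those of the drugs across genes, which are not independent replicates (Pearson 0.29 with tunicamycin at 5 µg/ml, 0.31 at 40 ng/ml, 0.30 with thapsigargin). Shared mock arrays alone gave 0.50 in simulation, and with mock arrays that share no array the values were -0.026, -0.064 and -0.056. Covariances differed from the simulated one by -0.000777, -0.00196 and -0.00165. The simulation took its spread from the fit to all 38 arrays. Arrays of a group differed by a standard deviation of 0.122 to 0.147 in BACE457 mock and of up to 0.262 in a1AT Tet. The simulated covariance may therefore be too large, and the negative differences show nothing about Tet and drug effects.

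**Figure D3:**
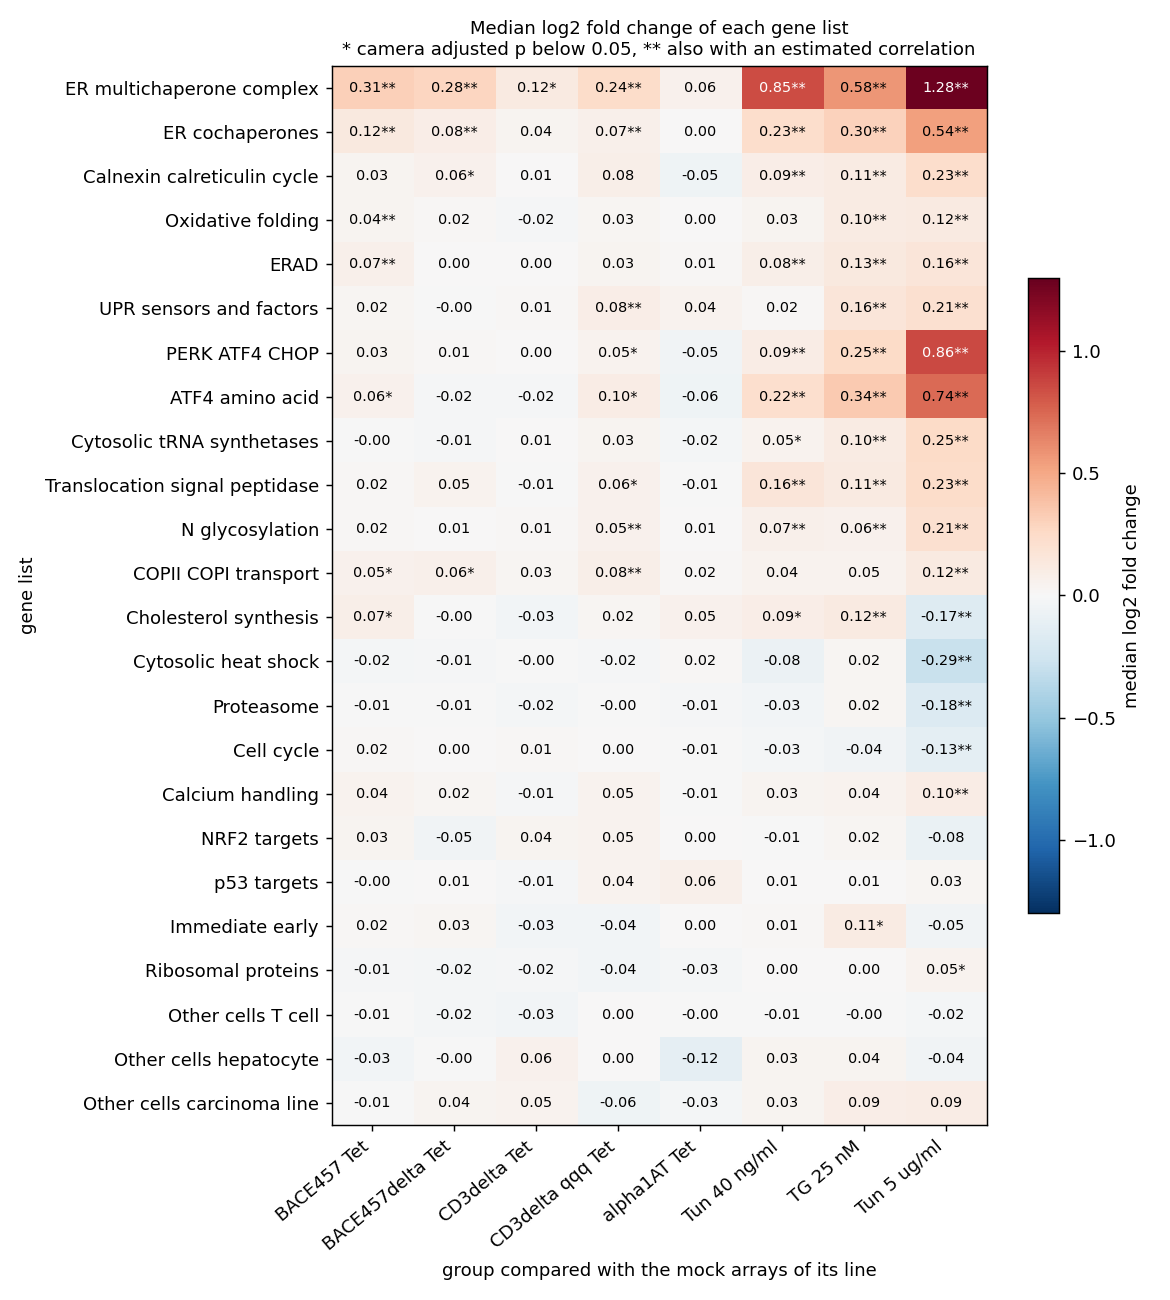
Median log2 difference (colour) of 24 gene lists (y axis) in 8 contrasts (x axis), with * for a camera adjusted p under 0.05 and ** where it also holds with an estimated correlation. The ER multichaperone complex has medians of 1.28, 0.85 and 0.58 with the 3 drugs. With Tet in the 5 lines they are 0.31, 0.28, 0.12, 0.24 and 0.06. All have the same sign with median scaling, which moves the median of all genes to 0.052 in CD3δ qqq and 0.053 in a1AT. With median scaling at 5 µg/ml tunicamycin the median of all genes is -0.078. There the medians of oxidative folding, ERAD, tRNA synthetases, COPII and COPI transport and calcium handling are negative. Those of ERAD, tRNA synthetases and calcium handling lie above that of all genes.

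Set directly against BACE457 Tet arrays, tunicamycin at 5 µg/ml gave 591 higher and 474 lower genes. DDIT3 was 2.24 ± 0.10 higher (4.72-fold, adjusted p = 6.96e-18), HSPA5 1.65 ± 0.20 higher (3.14-fold), and ETV5 differed by -2.06 ± 0.12 (other probe -0.569). Of the complex, 9 of 10 members were higher (10 over the list alone, 1.25e-25), and of the ATF4 amino acid genes 18 of 20 (19 over the list alone, 8.49e-42). Tunicamycin at 40 ng/ml gave 40 higher and 18 lower genes than Tet. CRELD2 was 0.86 ± 0.13 higher, ISL1, a homeobox factor, 0.81 ± 0.12, and ASNS 0.74 ± 0.09, while AMOT differed by -0.84 ± 0.12 and HSPA5 by 0.71 ± 0.20 (adjusted p = 0.127). Of the complex, 5 of 10 were higher (8 over the list alone, 2.51e-17; adjusted p = 0.00216 with an estimated correlation), but 4 of these calls were lost when single arrays were left out. Without BACE457 Tet 1 these were HSP90B1 (0.407), DNAJB11 (0.375), SDF2L1 (0.289) and PDIA4 (0.154). HSP90B1 was also lost without Tet 2 (0.0763) or 40 ng/ml array 1, 2 or 3 (0.169, 0.0973 and 0.136), DNAJB11 without array 2 or 3 (0.138 and 0.182), and SDF2L1 without array 1 or 3 (0.123 and 0.165). HYOU1 (0.63 ± 0.10) kept its call whichever array was left out. Thapsigargin gave 166 higher and 142 lower genes than Tet, led by LBH (1.86 ± 0.09; other probe 0.815), RGS2 (1.46 ± 0.14) and PPEF1 (2.38-fold), with AMOT at -1.22 ± 0.12 and HOXC9 at -0.68 ± 0.10. HSPA5 differed by 0.22 ± 0.20 (adjusted p = 0.784), and the complex list (1 of 10, 1 over the list alone, 3.75e-05) lost its call (adjusted p = 0.100 with an estimated correlation). The sign of the HSPA5 difference depends on BACE457 Tet 1. Without that array HSPA5 lay 1.12 ± 0.16 above mock with Tet, against 0.92 ± 0.20 with thapsigargin in the fit of all arrays.

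Drug and Tet arrays of the BACE457 line also differ in the number range of their titles, and Tet arrays all lie in the lower one. With that range as a term, resting on 1 mock array in the lower range, the counts were 171, 1 and 16. With median scaling they were 96 (36 higher, 60 lower), 1 and 24 (21 and 3). Of the single arrays, BACE457 Tet 1, 2 and 3 left 14, 29 and 36 genes for 40 ng/ml tunicamycin and 173, 143 and 185 for thapsigargin, and Tet 2 and 3 left 709 and 672 for 5 µg/ml. Tunicamycin arrays 2 and 3 at 40 ng/ml left 23 and 21, array 3 at 5 µg/ml left 621, and thapsigargin arrays 1 and 2 left 151 and 122.

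Between the tunicamycin doses, 315 genes were higher and 263 lower at 5 µg/ml. DDIT3 was 2.0 ± 0.10 higher (4.0-fold, adjusted p = 3.00e-16), INHBE 3.01-fold, TRIB3 2.86-fold and SLC6A9 2.75-fold (other probes 0.0861 and -0.0323 on the log2 scale), while HSPA5 was 1.92-fold higher and HSP90B1 differed by 0.33 ± 0.16 (adjusted p = 0.309). ETV5 was lower (-1.70 ± 0.12; other probe -0.333), as was ID1, an inhibitor of DNA binding (-1.08 ± 0.13; other probe -0.0171). Of the PERK-ATF4-CHOP targets, 14 of 20 were higher (17 over the list alone, 1.68e-42), of the ATF4 amino acid genes 15 of 20 (18; 4.04e-34), and of the complex 5 of 10 (9; 3.59e-12). The calls of COPII and COPI transport, immediate early genes and ribosomal proteins were lost (adjusted p = 0.0531, 0.114 and 0.0913 with an estimated correlation). With median scaling 13 genes were called (5 higher, 8 lower), and the count was 376 without 5 µg/ml array 3 and 298 and 343 without 40 ng/ml arrays 2 and 3.

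Thapsigargin against tunicamycin at 40 ng/ml gave 58 higher and 40 lower genes. LBH was 1.93 ± 0.09 higher (3.80-fold, adjusted p = 4.01e-18; other probe 0.738), PPEF1 2.48-fold (other probe 0.609 on the log2 scale), RGS2 2.43-fold, NEU1 2.01-fold and PTGS2, a prostaglandin synthase, 1.75-fold (other probe 0.163 on the log2 scale), while CRELD2 was lower (-0.65 ± 0.13, adjusted p = 0.00407), as was CGN, a tight junction protein (-0.55 ± 0.08). Of the complex no member passed over all genes (2 lower over the list alone), and its lower median (-0.21; 6.44e-05) lost its call (adjusted p = 0.155 with an estimated correlation). PERK-ATF4-CHOP targets were higher (1 of 20, 5 up and 1 down over the list alone, 3.02e-05), as were UPR sensors and factors (0.0114; 2 over the list alone), and carcinoma markers moved with them (1 of 5, 2 over the list alone, 0.0113). ATF4 amino acid genes (0.0153) and the proteasome (0.0113) lost their calls (adjusted p = 0.257 and 0.115 with an estimated correlation). With median scaling 16 genes were called, all higher, and the count was 53 without 40 ng/ml array 1 or 2, 53 without thapsigargin array 1 and 59 without array 2.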

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

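Of the tests in this part, those on the array labelled a1AT Tet 3 and on the 3 a1AT arrays apart from the rest were chosen after the results were seen, and those on tunicamycin dose were chosen before.

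The ER multichaperone complex rose more with Tet in the CD3δ qqq line than in the CD3δ line (median difference 0.13; camera adjusted p = 0.0154 for the difference of effects), as did ATF4 amino acid genes (0.12; 0.000843). Neither difference passed with an estimated correlation (adjusted p = 0.572 and 0.405 with an estimated correlation), and no single gene passed. Of 136 looks at fixed genes in pairs of lines (17 genes, 8 pairs), 5 showed all Tet arrays of one line above its mock mean and all of the other below it. DPAGT1 differed by -0.0812 in a1AT against 0.102 in CD3δ, 0.0682 in CD3δ qqq and 0.0635 in BACE457. PPIB differed by -0.0486 in CD3δ against 0.0901 in BACE457Δ and 0.160 in BACE457. These differences between lines were not tested.

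The array labelled a1AT Tet 3 had SERPINA1 0.105 above the mean of the mock arrays, while a1AT Tet 1 and 2 stood at 13.11 and 13.17. A dim array is argued against, since its share of detected probes exceeded the lowest of the line by 8.47 percentage points. A swap with a mock array of the line would leave a mock array at the induced level, and the mock arrays differed by 0.162. Mock RNA or an uninduced culture stays open and has the value it needs; a label error and a failed induction are not told apart by it.

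The 3 a1AT arrays apart from the rest are Tet 1, Tet 2 and mock 1. Induction of the transgene is argued against, because the mock array among them differed in SERPINA1 by -0.162 from the other mock array. Low signal cannot be told apart from other causes: the 3 had 44.6% to 47.8% of probes detected, and 1 other array lay below the highest of the 3. Their titles number them 8, 9 and 10, the lowest of the series, and the other 2 arrays of the line 11 and 12, which are the most alike mock and Tet arrays of any line (standard deviation of differences 0.106). A cause tied to the order of the arrays stays open and was not tested. No biological explanation was tested.

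More genes were called with tunicamycin at 5 µg/ml than at 40 ng/ml (1107 and 48). Without the dimmest array of the higher dose its count was 673, and the ratio to the 48 of the fit of all arrays was 14.02. In a fit chosen after seeing the data, without the 3 arrays in doubt, which include that array, the counts were 758 and 62. The ratio was 41.5 with median scaling, and against the mock arrays of the upper number range 28.1. These values argue against that array and the mock array of the lower range as the whole cause. They argue less firmly against quantile normalisation, since median scaling left few calls at 40 ng/ml. Arrays of the doses also differ in title number (55 to 63 at 5 µg/ml, 88 to 100 at 40 ng/ml). Dose cannot be told from a cause tied to the order of the arrays. The dose stays a hypothesis, tested on the same data.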

How the results depend on the processing

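The fits without 3 arrays in doubt together and with adjacent title numbers as a block were chosen after seeing the data. Contrasts are given in the order tunicamycin at 5 µg/ml, at 40 ng/ml and thapsigargin against mock, the same against BACE457 Tet, then 5 µg/ml and thapsigargin against 40 ng/ml.

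Median scaling called 83, 2, 20, 96, 1, 24, 13 and 16 genes, and the cause was not tested. A 1.5-fold minimum left 162, 19, 50, 134, 10, 45, 77 and 24, by its construction. Array weights called 2190, 252, 1783, 2194, 338, 1817, 1328 and 748, and 1 each in BACE457 and a1AT with Tet; the cause was not tested. Fitting only the compared groups gave 189 and 260 for 40 ng/ml against mock and Tet and 6 for BACE457Δ Tet, and all probes gave 2 for a1AT Tet. The number range term left 171, 1 and 16 against Tet. Without the 3 arrays in doubt the counts were 2 (CD3δ qqq), 4 (a1AT) and 700 (5 µg/ml against Tet). Blocks gave 7 in BACE457Δ and 1 in CD3δ.

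Leaving out each array gave 673 to 1004, 29 to 44, 155 to 485, 621 to 977, 14 to 41, 122 to 398, 298 to 555 and 53 to 98 genes, 0 to 9 in BACE457 Tet, 0 to 4 in a1AT Tet and 0 to 1 for the BACE457Δ difference. Where 1 mock array is left in a1AT, it is assumed to vary like the other groups. The complex list ran from 0.0233 to 0.0984 in CD3δ and 0.538 to 0.996 in a1AT. With fry it had an adjusted p of 0.0792 in BACE457Δ, 0.770 in CD3δ and 0.0719 in CD3δ qqq, and with an estimated correlation 0.458 in CD3δ. Correlations of BACE457 Tet with drugs across genes turned to -0.0257, -0.0640 and -0.0561 with controls that share no array. Those controls also match the title number range of each treated group. The positive values therefore depend on the choice of controls, and sharing and number range are not told apart.

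Of 3629 values of called named genes under alternatives, 3233 kept direction and threshold, 396 missed the threshold and 0 reversed. Leaving out single arrays gave 1320 of these values. Median scaling kept only 68 of its 220 values and missed the threshold for 152, so most named calls depend on the normalisation. A chip block was not run. Signal over background limits dim probes.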

Other observations

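The tests of HOX genes, ERK feedback genes, the Tet effect over 5 lines and the genes called with every drug were chosen after seeing the results, while those of thapsigargin-only genes and of other splits were chosen before.

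HOX genes, which encode homeobox patterning factors, lay among the falls. HOXC13 (-0.77 ± 0.10), HOXB6 (-0.72 ± 0.11) and HOXB5 (-0.68 ± 0.10) fell with tunicamycin at 5 µg/ml and drew attention to the family, so the test leaves out every member called with a drug. The 16 members left had a median of -0.091 at 5 µg/ml (14 below 0, camera p = 0.0118 with an estimated correlation) and of -0.081 with thapsigargin (11 below 0, p = 0.00250). At 40 ng/ml the p was 0.586. With median scaling the medians set against that of all genes were -0.059 and -0.098. The p-values of this camera test were not adjusted for the choice of family, and both contrasts share mock arrays. HOX genes may be slightly lower as a family with tunicamycin at 5 µg/ml and with thapsigargin. At 40 ng/ml the median was -0.025, so for tunicamycin this rests on the higher dose.

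The list called ERK feedback genes holds genes switched on by ERK signalling, of which only some restrain it. It includes ETV5, DUSP6, SPRED1 and SPRED2, which drew attention to the family. Of the 16 members, 14 fell with tunicamycin at 5 µg/ml, and of the 11 not named before, 9 fell (median -0.34). The camera test of limma, across genes and with an estimated correlation, gave p = 3.31e-05 for those not named before. With thapsigargin the p was 0.522. The list was written after the called genes were seen, and its p restates them. With members called with a drug left out, 2 remain, both above 0 (median 0.25), a choice made by the outcome as well. A fall of the family cannot be told from the choice of its members by these values.

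The 35 genes called with all 3 drugs had a median Tet difference of 0.12 in BACE457Δ (28 above 0), which shares no array with the drug contrasts, at percentile 100 of matched random lists. In CD3δ qqq the median was 0.18 (35 above 0), in CD3δ 0.049 (27) and in a1AT -0.010 (16, percentile 47.7). These genes may respond to both drugs and, in some lines, to Tet, where polypeptide and tetracycline are not separated. The 138 genes called with thapsigargin alone, turned to the thapsigargin direction, lay at percentile 40.9 in BACE457Δ, so no such response was seen there. They lay at 30.3 in CD3δ qqq, 54.6 in a1AT, 0.46 in CD3δ and 99.9 in BACE457, which shares mock arrays with the drug contrasts. Random lists draw genes independently, and genes that move together can reach either extreme. The percentiles of both gene sets are therefore descriptive.

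Over 5 lines, the mean Tet effect passed for 5 genes in limma, named after their values were seen. These were HSPA5 (0.46), PDIA4 (0.30), MANF (0.28), CRELD1 (0.26) and ARPC2 (-0.24). In the a1AT line they stood at 0.079, -0.10, -0.039, 0.050 and -0.31, so the rises of PDIA4 and MANF were not seen in every line. Of 100 shufflings of mock and Tet within lines, 19 called as many, the real one included, and the highest called 1800. What made that shuffling call so many genes was not tested. With 19 of 100 shufflings calling as many, an effect common to the lines cannot be told apart from other causes.

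Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real counts and the highest of the other splits were 1107 and 0 (5 µg/ml), 48 and 0 (40 ng/ml) and 316 and 4 (thapsigargin) against mock, 1065 and 0, 58 and 0, and 308 and 7 against Tet, 578 and 1 between doses, and 98 and 19 for thapsigargin against 40 ng/ml, with 1 split in 10 as high in each. In BACE457, BACE457Δ, CD3δ and CD3δ qqq with Tet, 10 of 10 splits gave 0 or more genes, with a real count of 0 and a highest other of 0. For both differences of Tet effects, 100 of 100 regroupings reached the real count of 0, with a highest other of 5 and 1. A real count of 0 is reached by any split, so these counts say nothing about chance.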
